A study of Mus musculus with 8 samples.

How the data were processed

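The authors deposited 1 table of FPKM for 8 libraries and 55188 entries named by gene symbol, and per the submitters' processing notes reads were aligned with STAR to mm10 and FPKM made with Cufflinks. The versions and settings of those tools are not given in the sources used here, nor is any normalisation beyond FPKM. Per the labels' protocols, libraries were made with a SMARTer mRNA kit and read in pairs on a NovaSeq instrument. Libraries were grouped by their titles, and the columns, named 46C or DIP2C with a series and day, were matched to the titles. For 4 samples the description names another library than the title does, and the title was followed. Eif2s3y, Ddx3y and Uty were above 0 in the 4 columns named 46C and at 0 in the 4 named DIP2C. The title of the WT-labelled N2B27 library gives day 6 and its column day 7. After joining 110 repeated entries, 55078 symbols were left, 24645 of them at 0 in all libraries. Symbols were matched to GENCODE M21 (GRCm38/mm10) for coordinates, and 97.8% of those tested had a single gene.

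Genes with an FPKM of at least 1 in at least 2 libraries were tested (15965), on log2 of FPKM plus 1, with limma 3.58.1 in R 4.3.3, with a trend on the mean in the eBayes step. The models, groups, gene lists and the rule for named genes were fixed before the data were examined. In the comparisons of labels the condition was a block, and in the comparisons of differentiation the series of each genotype was. Replicates are media or series, not repeats of a condition: KSR and N2B27 stood as replicates of differentiation, and both day 0 series as replicates of stem cells. In each of the 6 comparisons p-values were adjusted over the genes tested by the Benjamini-Hochberg method, and genes under 0.05 passed. The 32 gene lists, of at least 3 tested members each, were tested with camera at a preset correlation of 0.01 and adjusted over the lists of a comparison; beside it stand camera with an estimated correlation, with which 0 lists passed in any comparison, and fry. Intervals of limma are at 95%. Errors are standard errors of the fit, and SD over genes where so named. FPKM of a comparison are means over its libraries.

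Named genes were Dip2c and its paralogues, then the 10 per direction with the largest fitted change among genes past the test with the same sign in every pair, a mean of at least 5 FPKM on the higher side and a symbol that is not that of a predicted gene. Where fewer than 10 passed, the rest were filled from genes that did not, by the largest value of the smallest pair. In single pairs, which were compared without a test, they were the 5 per direction with the largest difference and at least 5 FPKM on the higher side, and genes were counted at a 2-fold difference. Medians of lists in single pairs were placed among those of 10000 random lists matched for expression, with a fixed seed, which describes these libraries and is no p-value. Scaling by the median log2 ratio replaced a planned scaling of counts, and a planned test of counts was not run, because the table holds FPKM. Other pseudocounts, filters, scalings, eBayes settings and left-out pairs were tried as alternatives. Tubb3, Foxf1, Foxc2, Dux, Tex13, Nespas, Mvd and Slc7a5 were in the lists and not analysed here. Members of lists named as examples, Eif2s3x and the predicted genes Gm14541 and Gm7618 lie outside the rule and were chosen after their values were seen. The values of 1 gene that the rule picked in a single pair and of 1 list member are not reported here.

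The fits were tested on simulated data with 50 genes changed at each of 4 sizes, log2 1, 2, 3 and 4, among 14879 to 14908 genes. All changed genes had a mean log2 of FPKM plus 1 of at least 5. Recovery of genes below that, Dip2c among them, was not tested. The comparison over 4 conditions recovered 92%, 100%, 100% and 100% of the changed genes, with 7 other genes called. Day 0 recovered 48%, 94%, 94% and 96%, with 2 others, and differentiated cells 62%, 90%, 98% and 100%, with 6 others. The test of the difference recovered 12%, 88%, 94% and 100%, with 8 others. Differentiation recovered 58%, 88%, 98% and 100% in WT-labelled cells, with 3 others, and 58%, 92%, 100% and 100% in KO-labelled cells, with 5 others. In all 6 comparisons the simulated spread of a gene was that of the label fit over 4 conditions. In the data the median standard error was 0.264 for differentiation and 0.196 for the labels at day 0. Recovery for differentiation was thus tested at a smaller spread than that of the data. A list of 30 genes raised by 0.5 was called in all 6 comparisons, with 0 other lists. Genes were simulated independently of each other, so false calls through correlation within a list could not arise and were not tested. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the other steps.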

Results

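Messenger RNA was sequenced from mouse embryonic stem cells of the line 46C and from cells carrying a deletion of Dip2c, a gene of the disco-interacting protein 2 family, in 8 libraries. Each genotype was sampled in a KSR series, in stem cell medium at day 0 and in KSR induction medium at day 4, and in an N2B27 series, at day 0 and in N2B27 medium at day 6. Both media are used to turn stem cells into neural cells. The column of the WT-labelled N2B27 library is named day 7, whereas its label gives day 6, and this pair is called N2B27 day 6 throughout. There was 1 library per genotype and condition, and the 2 day 0 pairs share the stem cell medium. The values were FPKM without counts, so the read depth is unknown. The FPKM of a library summed to 508556 to 635836, between 13451 and 14329 genes reached an FPKM of 1, and mitochondrially encoded genes held 5.19% to 6.58% of the sum.

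Dip2c (ENSMUSG00000048264.16, chromosome 13:9276528-9668928 of GRCm38/mm10) was read in all 8 libraries, whatever their label. Its FPKM was 3.69 in the WT-labelled and 3.33 in the KO-labelled library at KSR day 0, and 4.86 and 4.43 at KSR day 4. At N2B27 day 0 it was 2.74 and 2.91, and at N2B27 day 6 5.78 and 4.43, so the KO-labelled libraries held 76.6% to 106% of the mRNA of their WT-labelled partners. The fitted difference was −0.12 ± 0.13 log2 (standard error, n = 4 pairs; 95% interval −0.43 to 0.19; limma adjusted p = 0.948). FPKM of a whole gene do not show which exons were read. Because the mRNA of Dip2c did not separate the labels, every library is named by its label, and each direction given is one between labels. The paralogues Dip2a and Dip2b differed by 0.10 ± 0.13 and 0.14 ± 0.13, with 95% intervals of −0.20 to 0.39 and −0.17 to 0.44, and none of these 3 genes passed the test, over all genes or adjusted over the list alone.

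The labels did divide the libraries by some genes of the Y chromosome. Eif2s3y, a Y-linked subunit of a translation initiation factor (chromosome Y:1010543-1028847), had 14.9, 8.56, 7.03 and 8.94 FPKM in the WT-labelled libraries of KSR day 0, KSR day 4, N2B27 day 0 and N2B27 day 6, and was listed at 0 in the 4 KO-labelled libraries. Its X-linked partner Eif2s3x had 50.1 to 72.0 FPKM in the WT-labelled and 54.2 to 72.3 in the KO-labelled libraries. Ddx3y and Uty were likewise listed at 0 in all KO-labelled libraries and had up to 5.29 and 1.15 FPKM in the WT-labelled ones. Of the 11 tested genes assigned to the Y chromosome 4 were at 0 in all KO-labelled libraries and 7 above 0 in all of them, and the median by label of the 11 lay between −0.22 and 0.02 log2 in the 4 pairs.

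**Figure D1:**
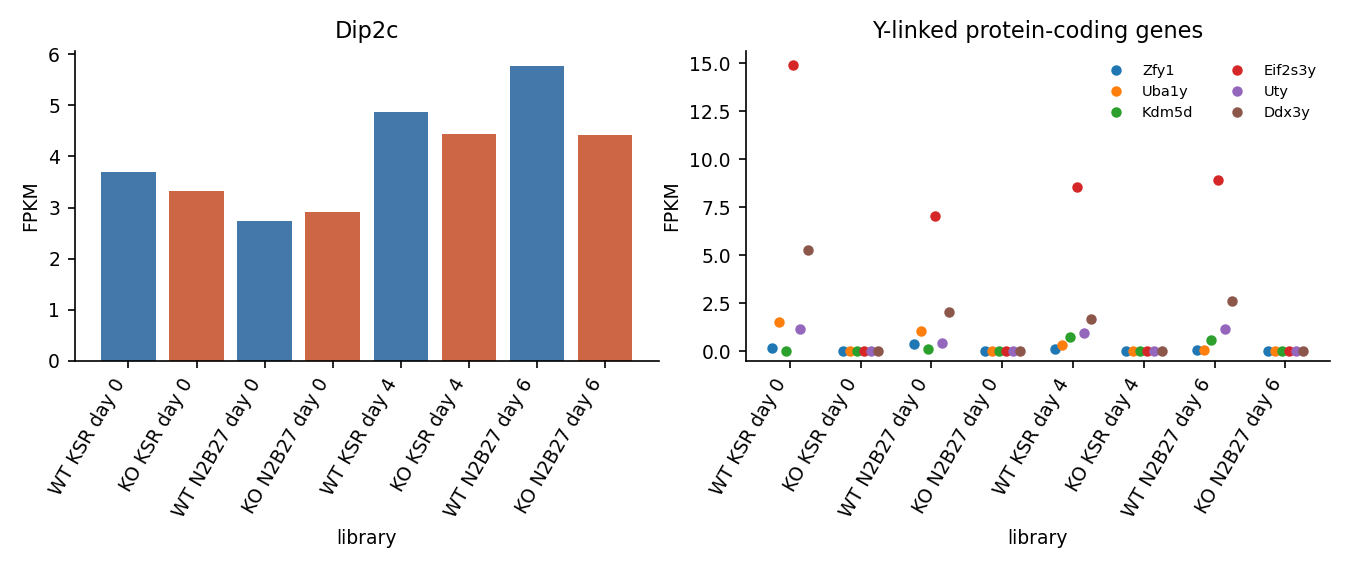
FPKM of Dip2c (bars, 1 per library, blue for the WT label and orange for the KO label) and of 6 Y-linked protein-coding genes (points, 1 per gene and library) in the 8 libraries. Dip2c lies between 2.74 and 5.78 under both labels, whereas Eif2s3y is at 0 in all 4 KO-labelled libraries.

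What neural induction did to each genotype was asked first, by comparing the differentiated libraries with day 0 within a genotype (n = 2 pairs each, KSR and N2B27). The WT-labelled cells lost the transcripts of naive stem cells and gained those of neural progenitors and neurons. Of the 15965 genes tested, 2717 rose and 2112 fell, and 2209 and 1624 of these did so by at least 2-fold. The growth factor gene Ptn, listed at 0 in both day 0 libraries, reached 284 FPKM (7.99 ± 0.36 log2). The imprinted gene Nnat rose from 2.95 to 784 FPKM (7.63 ± 0.19) and Irx3, a homeobox gene of the neural plate, from 0.408 to 145 (6.68 ± 0.21). The retinoic acid binding protein gene Crabp2 rose from 4.05 to 411 (6.35 ± 0.18). Fabp7, Nr2f1, Sox3, Sox11, Ccnd2 and H19 rose by 6.14 to 7.32 log2. Among the genes that fell, the homeobox gene Crxos went from 122 to 0.0472 FPKM (−6.84 ± 0.24), and Spp1 from 371 to 3.08 (−6.52 ± 0.31). Tdgf1, a Nodal co-receptor, fell from 359 to 3.59 (−6.28 ± 0.27) and Tdh, threonine dehydrogenase, from 297 to 3.01 (−6.23 ± 0.37). Tcl1, Nupr1, Esrrb and Tfcp2l1 fell by 5.89 to 6.08 log2. Tdgf1-ps1 and Rpl10l also fell, but as near copies of Tdgf1 and of Rpl10 they can share reads with them, so their values are uncertain. Log2 values were taken after adding 1 to each FPKM, so those of genes at or near 0 on one side depend on that addition and are no bound. Without the WT N2B27 pair 1409 genes passed and without the WT KSR pair 2369, against 4829 with both.

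The naive pluripotency genes formed the group with the lowest mean in WT-labelled cells. Of the 18 measured, 16 fell and 0 rose, and 17 fell adjusted over the list alone. The mean was −4.51 (SD 1.88 over genes; camera adjusted p = 6.42e-11, adjusted p = 0.416 with an estimated correlation). Esrrb (−5.94), Tfcp2l1 (−5.89) and Nanog (−5.69) were among those that fell, and Dppa3 and Gbx2 did not pass. Of the 15 general pluripotency genes 8 fell, among them Pou5f1 (−4.62), and 2 rose, Lin28a and Lin28b, which are kept on in neural progenitors. Adjusted over the list alone 10 fell and 2 rose (mean −1.82; adjusted p = 0.003, adjusted p = 0.644 with an estimated correlation). Sox2, which serves both stem cells and neural progenitors, had −0.59 and did not pass. Of 21 germline genes that DNA methylation silences in somatic cells, 10 fell and 0 rose, the same numbers adjusted over the list alone (mean −1.74; adjusted p = 3e-05, adjusted p = 0.416 with an estimated correlation), with Tuba3a at −5.40 and Dazl at −4.38. In the integrated stress response list 8 of 18 fell, 9 adjusted over the list alone, among them Asns (−3.49), Trib3 (−3.39) and Chac1 (−3.29). The mean was −1.12 (adjusted p = 0.00304, adjusted p = 0.637 with an estimated correlation).

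Of 35 neuronal differentiation genes, 32 rose in WT-labelled cells and 33 did adjusted over the list alone, with a median of 3.07 (SD 1.48 over genes; camera adjusted p = 8.06e-11, adjusted p = 0.637 with an estimated correlation). The growth cone gene Gap43 rose by 5.12, the proneural factor gene Neurog2 by 3.91, Map2 by 4.39 and Dcx by 3.24, whereas Mapt, Stmn2 and Stmn3 did not pass. Of 27 neural progenitor genes 20 rose and 1 fell, Hesx1, a gene of the early anterior epiblast. Adjusted over the list alone 21 rose and 1 fell (mean 3.37; adjusted p = 1.53e-09, adjusted p = 0.416 with an estimated correlation). Cdh2 rose by 6.12, Pax6 by 5.78, Sox1 by 3.59 and Nes, the intermediate filament gene of progenitors, by 3.20. Of 12 genes in the Notch target list 9 rose and 1 fell, Dtx1, the same adjusted over the list alone. Hes5 had 5.24 (list mean 2.46, camera adjusted p = 0.000989, adjusted p = 0.637 with an estimated correlation). The list also holds genes of Notch ligands and receptors, among them Dll1 (5.40), which is a member of the neuronal list too. Among 15 retinoic acid targets 8 rose, 9 adjusted over the list alone, such as Cyp26b1 (5.70) and Meis1 (5.30), and 1 fell, Cdx1, joined by Stra8 and Dhrs3 adjusted over the list alone (mean 2.16; adjusted p = 0.00632, adjusted p = 0.637 with an estimated correlation). Of 27 imprinted genes 13 rose, 14 adjusted over the list alone, such as Mest (5.43) and Peg10 (5.23), and 1 fell, Slc22a18 (mean 1.95; adjusted p = 0.000936, adjusted p = 0.416 with an estimated correlation).

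Markers of other cell types moved in the same libraries. Of 18 endoderm genes 7 rose, 8 adjusted over the list alone, such as Cxcr4 (5.33) and Foxa2 (4.42), with a mean of 2.49 (adjusted p = 0.000936, adjusted p = 0.753 with an estimated correlation). Of 13 fibroblast genes 6 rose and 1 fell, Fn1, or 8 and 1 adjusted over the list alone, with the smooth muscle genes Acta2 at 5.27 and Tagln at 4.98 (mean 1.74; adjusted p = 0.0117, adjusted p = 0.637 with an estimated correlation). Of 13 neural crest genes 6 rose, among them Zeb2 (5.11) and Pax3 (4.48), and 2 fell, Foxd3 and Ngfr, or 7 and 2 adjusted over the list alone (mean 2.11; adjusted p = 0.0339, adjusted p = 0.637 with an estimated correlation). In the formative epiblast list 7 of 16 rose, such as Pou3f1 (3.96) and Dnmt3a (2.21), and 2 fell, Etv5 and Nodal, joined by Etv4 adjusted over the list alone, where 9 rose (mean 1.41; adjusted p = 0.0230, adjusted p = 0.753 with an estimated correlation). Of 22 cholesterol synthesis genes 9 rose and 0 fell, or 11 and 0 adjusted over the list alone, such as Hmgcs1 (1.44; mean 0.55; adjusted p = 0.0192, adjusted p = 0.637 with an estimated correlation). Without the WT N2B27 pair the calls of the endoderm, neural crest and cholesterol lists were lost, with means of 1.11, 1.42 and 0.38, and without the WT KSR pair that of the formative list, with a mean of 1.05. The other lists had adjusted p of 0.0644 or more as groups. Of those, Hox genes went both ways: of 12, the anterior genes Hoxa2, Hoxa3, Hoxb1, Hoxb2 (5.50) and Hoxb3 rose and Hoxb9 (−2.58), Hoxc4 and Hoxc10 fell, the same 5 and 3 in number adjusted over the list alone.

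The KO-labelled cells went through the same broad change. In them 2621 genes rose and 1741 fell, 2132 and 1422 by at least 2-fold. Ptn rose from 0.0224 to 282 FPKM (8.09) and Nnat from 3.76 to 547 (6.80). Crabp1, a retinoic acid binding protein gene, rose from 18.9 to 1191 FPKM (6.18 ± 0.64), and Tagln from 0.118 to 73.2 (6.03 ± 0.25). Fabp7, Crabp2, Nr2f1, Sox3, Irx3 and Ccnd2 rose by 6.01 to 6.73. Klf4, a transcription factor of the naive state, fell from 238 to 2.65 FPKM (−6.05 ± 0.91) and Zfp42 from 251 to 3.94 (−5.94 ± 0.46). Crxos, Tdh, Tfcp2l1, Esrrb, Tdgf1 and Spp1 fell by 5.90 to 6.82, and the near copies Rpl10l and Tdgf1-ps1 fell as well. Without the KO N2B27 pair 1744 genes passed and without the KO KSR pair 2003, against 4362 with both.

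By gene group, 16 of 18 naive pluripotency genes fell in KO-labelled cells, the same number adjusted over the list alone (mean −4.75; camera adjusted p = 2.34e-13, adjusted p = 0.378 with an estimated correlation). Of the neural progenitor genes 18 of 27 rose, 21 adjusted over the list alone (mean 3.11; adjusted p = 2.70e-08, adjusted p = 0.378 with an estimated correlation), with Cdh2 at 5.97, Pax6 at 5.38 and Sox1 at 3.97. Of the neuronal genes 25 of 35 rose and 1 fell, Stmn2, or 27 and 1 adjusted over the list alone (median 2.26; adjusted p = 2.59e-07, adjusted p = 0.714 with an estimated correlation). Gap43 rose by 4.42, Map2 by 3.63 and Dcx by 2.43, while Neurog2 had 1.99 and did not pass. Of 21 germline genes 8 fell, 11 adjusted over the list alone (mean −1.91; adjusted p = 2.59e-07, adjusted p = 0.378 with an estimated correlation). General pluripotency, Notch, retinoic acid, imprinted, fibroblast, endoderm, formative, stress response and cholesterol genes passed as groups in the direction they had in WT-labelled cells, with means of −1.77, 2.16, 2.27, 1.75, 2.11, 2.01, 1.41, −0.61 and 0.52. Their adjusted p = 0.555 or more with an estimated correlation. The trophoblast list passed as well (mean −0.67; adjusted p = 0.0396, adjusted p = 0.734 with an estimated correlation), Tfap2c, Gata2, Grhl3, Esx1 and Ascl2 of its 13 genes falling and Krt18 rising, joined by Eomes and Krt8 adjusted over the list alone. The neural crest list, called in WT-labelled cells, did not pass as a group in KO-labelled cells. Its medians there were 1.62 in the KSR pair and 2.84 in the N2B27 pair. Of 15 general pluripotency genes 8 fell and Lin28a and Lin28b rose, and of 18 stress response genes 7 fell and Phgdh and Vldlr rose. Adjusted over the list alone 8 and 8 fell and the same genes rose. Of 12 Notch targets 8 rose, of 15 retinoic acid targets 9, of 27 imprinted genes 11, of 13 fibroblast genes 7, of 16 formative genes 8 and of 22 cholesterol synthesis genes 8, which were 9, 9, 14, 9, 9 and 10 adjusted over the list alone. Against these Dtx1 of the Notch targets, Cdx1 of the retinoic acid targets, Zrsr1 and Ascl2 of the imprinted, Fn1 of the fibroblast and Etv5 and Nodal of the formative genes fell. Adjusted over the list alone they were joined by Stra8, Igf2r and Etv4 of the retinoic acid, imprinted and formative lists. Of 18 endoderm genes Cxcr4, Dab2, Foxa2, Lamb1 and Cubn rose, and 6 did adjusted over the list alone. Of 9 blood and endothelium genes 3 rose, the embryonic globins Hba-x (2.71) and Hbb-bh1 (2.62) and the globin Hba-a1 (2.29), and 1 fell, Pecam1, the same adjusted over the list alone. Without the KO KSR pair the calls of the formative, trophoblast and stress response lists were lost, with means of 0.72, −0.29 and −0.36, the trophoblast call also with median log2 ratio scaling (adjusted p = 0.0629), and without the KO N2B27 pair those of the endoderm and cholesterol lists, with means of 1.42 and 0.47.

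Both genotypes shared most of this response. Of the genes called in either, 2189 rose and 1546 fell in both, against 446 and 230 if the calls were independent, and 0 were called in opposite directions. Both responses came from 1 fit with a shared spread per gene, so the calls are not independent and that expectation is no baseline. Across genes the log2 changes of the 2 genotypes had a Pearson r of 0.949 and a Spearman rho of 0.920; genes are not independent replicates. Of 1094 genes called in WT-labelled cells alone, 1077 had the same sign in KO-labelled cells, so a call in 1 genotype does not show a difference, which the test of the difference itself addresses.

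**Figure D2:**
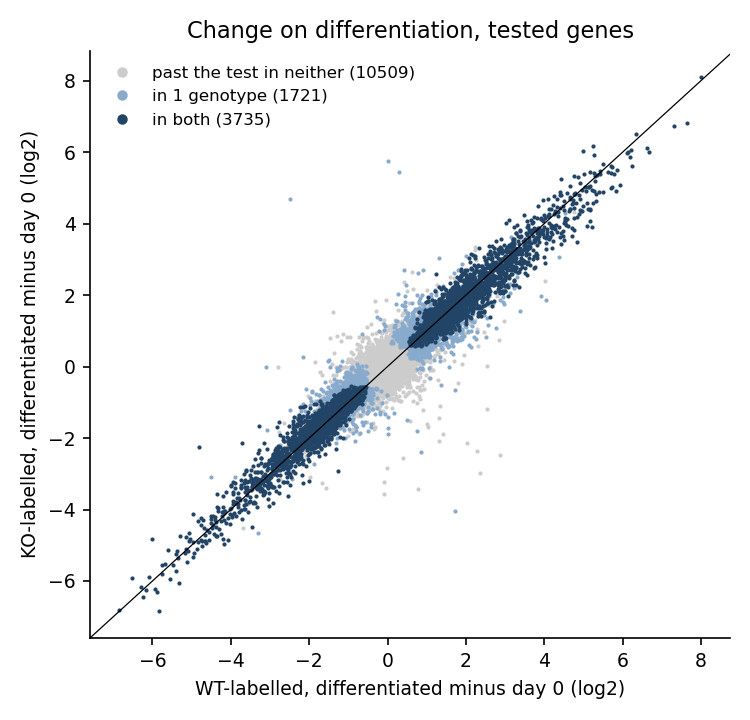
Log2 change on differentiation in WT-labelled (x axis) and KO-labelled cells (y axis), 1 point per tested gene, coloured by whether it passed in both genotypes, in 1 or in neither. Genes that passed in both lie in the lower left or the upper right, and 0 lie in the other corners.

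Genes that differed by label in all 4 conditions were sought with the condition as a block (n = 4 pairs). Eif2s3y passed, at 9.86 FPKM on average in WT-labelled libraries and listed at 0 in KO-labelled ones (fitted −3.39 ± 0.19; adjusted p = 0.00747), and no other gene did. In all, 694 genes had an unadjusted p under 0.05, where 798 are expected by chance. Without the KSR day 4, the N2B27 day 0 or the N2B27 day 6 pair 0 genes passed in limma. Phlda2, an imprinted gene that restrains growth of the placenta, had 11.5 FPKM under the WT and 3.38 under the KO label (−1.43 ± 0.24; adjusted p = 0.699). Ccar1, a regulator of cell cycle and apoptosis, had 37.1 and 62.5 (0.76 ± 0.11; adjusted p = 0.433). Lmo1 had 5.72 and 2.25 FPKM, the immediate early gene Egr1 148 and 108, and Zfp930 8.61 and 14.0. Fmnl3, Fhl3, Foxp1, Tnk2, Mbtps2, Naa16 and Ptgfrn had 0.27 to 0.58, and Slc35b2, Pigbos1 and Commd9 −0.53 to −0.46, with adjusted p of 0.680 to 0.945. The 7SL RNA genes Rn7s1 (−0.84) and Rn7s2 (−0.81; both adjusted p = 0.141), Mpc1-ps (−0.82) and Rpl37-ps1 (1.42) have near-identical copies in the genome, so their values are uncertain. Of the tested genes 12.2% had the same sign in all 4 pairs, where chance gives 12.5%, and the differences of 2 pairs correlated across genes by −0.05 to 0.04.

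Of the lists, neuronal genes had negative values in all 35 members, with a mean of −0.38 (SD 0.18 over genes; camera adjusted p = 1.68e-06, adjusted p = 0.958 with an estimated correlation), and 0 of the 35 passed in limma, over all genes or adjusted over the list alone. Endoderm genes had a mean of −0.28, negative in all 18 (adjusted p = 0.00250), and naive pluripotency genes one of −0.20, negative in 16 (adjusted p = 0.0196). Both had adjusted p = 0.958 with an estimated correlation. These values rested on the N2B27 day 6 pair, without which the means were 0.01, 0.03 and −0.01. The endoderm call was also lost with a pseudocount of 0.1 (adjusted p = 0.0935) and the naive pluripotency call without chromosomes 8 and Y (adjusted p = 0.0658). Glycolysis and hypoxia genes had a mean of 0.18, positive in 21 of 27 (adjusted p = 1.69e-06, adjusted p = 0.958 with an estimated correlation), for example Slc16a3, a lactate transporter gene (0.56), and Slc2a1, a glucose transporter gene (0.35). The pairs did not agree on it, with medians of −0.11 at KSR day 0, where 7 of the 27 were positive, 0.44 at KSR day 4, 0.10 at N2B27 day 0 and 0.30 at N2B27 day 6. The mean was 0.09 without the KSR day 4 pair (adjusted p = 0.0310) and 0.27 without the KSR day 0 pair. Stress response genes had −0.15 (adjusted p = 0.0181, adjusted p = 0.958 with an estimated correlation), which was 0.04 without the N2B27 day 0 pair. The Y and X inactivation list had −1.25 (adjusted p = 1.68e-06, adjusted p = 0.393 with an estimated correlation), and Eif2s3y, Ddx3y and Uty passed adjusted over the list alone. So did Phlda2 and Cdkn1c of the 27 imprinted genes and Egr1 of the 16 FGF and ERK targets, whose lists did not pass.

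Stem cells at day 0 were compared by label over the KSR and N2B27 series (n = 2 pairs). The gene that passed was Gm14541 (chromosome X:36839137-36839293), a processed pseudogene with 56.2 and 68.5 FPKM in the WT-labelled libraries and listed at 0 in both KO-labelled ones (adjusted p = 0.0109). Its 157 bases can share reads with other copies, so its value is uncertain. It had 72.3 and 24.7 FPKM in the differentiated KO-labelled libraries, and 0 genes passed at day 0 with any of the 4 pairs left out. In this comparison 739 genes had an unadjusted p under 0.05. Ccar1 had 31.7 FPKM under the WT and 62.8 under the KO label (0.97 ± 0.11; adjusted p = 0.285), the sterol enzyme gene Lss 17.2 and 40.0 (1.15 ± 0.29). The transferrin receptor gene Tfrc had 73.4 and 123 (0.70 ± 0.13), and Lef1, a Wnt effector and target, 2.62 and 6.84 (0.94 ± 0.22; last 3 adjusted p = 0.931). Phlda2 had 17.4 and 4.28 (−1.83 ± 0.29; adjusted p = 0.790), and S100a10 42.4 and 22.7 (−0.88 ± 0.12; adjusted p = 0.513). The interferon-induced Bst2 had 35.8 and 16.4 (adjusted p = 0.782) and Bola3 49.9 and 15.9. Lysmd3, Slc16a9, Iqsec1, Klf12 and Kcnh3 had 0.67 to 0.96, and Slc7a7, Rn7sk and Mettl21a −1.07 to −0.76.

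At day 0 all 18 integrated stress response genes had negative values (mean −0.41; SD 0.22 over genes; camera adjusted p = 1.92e-06, adjusted p = 0.968 with an estimated correlation), and 0 passed in limma over all genes or adjusted over the list alone. The N2B27 pair carried most of it. There Chac1 had 50.2 FPKM under the WT and 20.7 under the KO label, Trib3 63.0 and 32.7 and the serine synthesis gene Psat1 272 and 157. Without that pair the mean was −0.11 (adjusted p = 0.259). Wnt targets had a mean of 0.22, positive in 11 of 15 (adjusted p = 0.00337, adjusted p = 0.968 with an estimated correlation), which was 0.17 without the N2B27 day 0 pair (adjusted p = 0.120). Axin2 and Lef1, at 0.56 and 0.94, were the 2 genes that passed adjusted over the list alone. The Y and X inactivation list had −1.27 (adjusted p = 0.00130, adjusted p = 0.968 with an estimated correlation), and its call was lost without the KSR day 4 pair (adjusted p = 0.107) or the N2B27 day 6 pair (adjusted p = 0.0694), which lend this comparison their spread. Of 27 imprinted genes Plagl1, Peg10 and Impact were higher and Phlda2, Slc22a18 and Gnas lower adjusted over the list alone, and 0 passed in limma over all genes. Pluripotency, progenitor and neuronal genes had means of −0.14 to 0.01, with adjusted p = 0.854 for each list.

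After differentiation the libraries were compared by label over KSR day 4 and N2B27 day 6 (n = 2 pairs), to ask whether the induced cells differed. The gene that passed was Gm7618 (chromosome 6:148900968-148901138), a processed pseudogene listed at 0 in both WT-labelled libraries, with 51.0 and 54.8 FPKM in the KO-labelled ones (adjusted p = 0.00225). Reads of near-identical copies make its value uncertain. With any of the 4 pairs left out 0 genes passed, and 697 had an unadjusted p under 0.05. Cdkn1c, an imprinted inhibitor of the cell cycle, had 63.9 FPKM under the WT and 18.3 under the KO label (−2.10 ± 0.33; adjusted p = 0.743). Gsx1, a homeobox gene of neural progenitors, had 40.5 and 8.23 (−1.59 ± 0.34), and the immediate early genes Fos and Fosb 35.7 and 7.96 (−1.57 ± 0.33) and 23.2 and 1.76 (−2.36 ± 0.50). Nckap5 and Dock3 had −0.98 and −0.97. Hba-x had 0.366 and 6.19 FPKM (2.29 ± 0.42), Mogat2 5.30 and 11.5, Prpf40b 27.5 and 48.1, and Pdk1, Aldoc, Impa2 and Mgarp 0.73 to 0.89 log2. The adjusted p of these genes were 0.743 or more. Rpl38-ps1, Uqcrh-ps1 and Usf2-ps1 are copies of other genes and their values, −3.31, 1.21 and −1.09, are uncertain.

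Neuronal genes had negative values in all 35 members after differentiation, with a mean of −0.75 (SD 0.32 over genes; camera adjusted p = 3.80e-16, adjusted p = 0.806 with an estimated correlation), and 0 passed in limma over all genes or adjusted over the list alone. Endoderm genes had −0.52 (adjusted p = 1.18e-06), naive pluripotency genes −0.32 (adjusted p = 0.000809) and Notch targets −0.32 (adjusted p = 0.00203), each with adjusted p = 0.806 with an estimated correlation. Neural progenitor genes had −0.25 (adjusted p = 0.000394, adjusted p = 0.702 with an estimated correlation). Without the N2B27 day 6 pair the means of these lists were 0.06, 0.17, 0.15, −0.09 and −0.10, and of them the endoderm list alone passed, upwards (adjusted p = 0.0379). Without the KSR day 4 pair they were −1.56, −1.21, −0.79, −0.55 and −0.39. Glycolysis genes had a mean of 0.34, positive in 23 of 27 (adjusted p = 1.97e-11, adjusted p = 0.702 with an estimated correlation), with Ddit4 at 0.88, Slc16a3 at 0.87 and Pdk1 at 0.82. Of the list Pdk1, Pgk1 and Aldoa passed adjusted over the list alone, and the list passed with each pair left out. p53 targets had 0.26, positive in 16 of 20 (adjusted p = 9.53e-05, adjusted p = 0.806 with an estimated correlation), or 0.09 without the N2B27 day 6 pair (adjusted p = 0.221). Fibroblast genes had 0.22 (adjusted p = 0.0433, adjusted p = 0.866 with an estimated correlation), and their call was lost without the KSR day 0, N2B27 day 0 or N2B27 day 6 pair, at 0.03 without the last. It was also lost with a pseudocount of 0.1 (adjusted p = 0.179) and without chromosomes 8 and Y (adjusted p = 0.0760). The Y and X inactivation list had −1.22 (adjusted p = 7.47e-06, adjusted p = 0.702 with an estimated correlation). Adjusted over the list alone, Eif2s3y, Ddx3y and Uty of that list, Hba-x and Hba-a1 of the 9 blood genes, Cdkn1c of the imprinted genes, Egr1 and Fos of the FGF and ERK targets and Aldoc of the 10 glial genes passed.

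Whether differentiation itself differed by label was tested as the KO minus WT difference after differentiation minus that at day 0. Gm7618 passed (5.75; adjusted p = 0.0169), 0 genes passed in limma with any of the 4 pairs left out, and 679 genes had an unadjusted p under 0.05. Bst2 had a difference of 1.62 ± 0.21, Pdk1 of 1.04 ± 0.18, Peg10, an imprinted gene derived from a retrotransposon, of −1.33 ± 0.23, Gata2 of −1.66 ± 0.49 and Gsx1 of −1.62 ± 0.48. Rexo5, Tmem141, Anxa2, Mogat2, Gprc5a, Def6, Got1l1 and Mettl21a had 1.18 to 1.57, and Cdkn1c, Lifr, Mus81, Ap3b2 and Frmd4a −1.47 to −1.08. All had adjusted p = 0.917. Adjusted over the list alone, Pdk1, Peg10 and Aldoc passed in the glycolysis, imprinted and glial lists. The rise of neuronal genes was smaller under the KO label, with a mean difference of −0.74 (camera adjusted p = 5.15e-11, adjusted p = 0.877 with an estimated correlation), and 0.07 without the N2B27 day 6 pair. Stress response genes had a mean difference of 0.52 (adjusted p = 4.38e-05, adjusted p = 0.877 with an estimated correlation), or 0.22 without the N2B27 day 0 pair (adjusted p = 0.149). p53 targets had 0.44 (adjusted p = 3.06e-05, adjusted p = 0.877 with an estimated correlation), or 0.31 without the KSR day 0 pair (adjusted p = 0.125). Glycolysis genes had 0.33 (adjusted p = 1.74e-05, adjusted p = 0.857 with an estimated correlation), or 0.21 without the KSR day 0 pair (adjusted p = 0.125) and 0.24 without the KSR day 4 pair (adjusted p = 0.0640). Of the other lists endoderm (−0.48), Wnt (−0.34), Notch (−0.31), progenitor (−0.25), naive pluripotency (−0.24), imprinted (−0.20) and germline genes (−0.17) passed, with adjusted p = 0.857 or more with an estimated correlation. Each of these 7 lost its call without the N2B27 day 6 pair, at 0.21, −0.16, −0.08, −0.10, 0.23, −0.12 and 0.06, and the germline list stood at 0.10 without the KSR day 0 pair. Calls were also lost without the KSR day 0 pair by the Notch, progenitor, naive and imprinted lists, at −0.28, −0.24, −0.20 and −0.14, and without the N2B27 day 0 pair by the endoderm, Notch, Wnt and naive lists, at −0.39, −0.33, −0.29 and −0.27. The Notch call was lost with a pseudocount of 0.1 (adjusted p = 0.119) and the germline call with median log2 ratio scaling (adjusted p = 0.0668).

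In single pairs, which hold 1 library per label and so no test, the N2B27 day 6 pair stood apart. In it 784 genes differed by at least 2-fold, against 228 at KSR day 4, 284 at KSR day 0 and 373 at N2B27 day 0. The neuronal list had a median of −1.57 at N2B27 day 6, below all of 10000 random lists matched for expression, and one of 0.12 at KSR day 4. At N2B27 day 6 Neurog2 had 47.3 FPKM under the WT and 4.09 under the KO label. Nefm, a neurofilament gene, had 140 and 28.8, Gap43 92.1 and 21.5 and Dcx 21.7 and 4.69. Progenitor genes stood closer, with a list median of −0.37. Of the 27, 10 were higher under the KO label, such as Nes at 84.3 and 89.6 and Zic1 at 143 and 186, and the others lower, such as Irx3 at 182 and 88.2 and Fabp7 at 358 and 205. Markers of other fates moved in the same pair. Endoderm genes had a median of −1.24, with Sox17 at 56.9 and 21.2 and Col4a1 at 240 and 93.4. Naive pluripotency genes had one of −0.73, with Klf4 at 19.8 and 3.43, and Pou5f1 had 17.7 and 6.70. Fibroblast genes had a median of 0.51, with Acta2 at 51.2 and 108, and p53, glycolysis and cell cycle genes 0.50, 0.30 and 0.27. Fosb had 43.6 and 2.92 FPKM and Pcp4 11.8 and 0.372. The globins Hba-x, Hbb-bh1 and Hba-a2 had 0.117 and 9.16, 0.352 and 10.9, and 0.313 and 7.15.

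**Figure D3:**
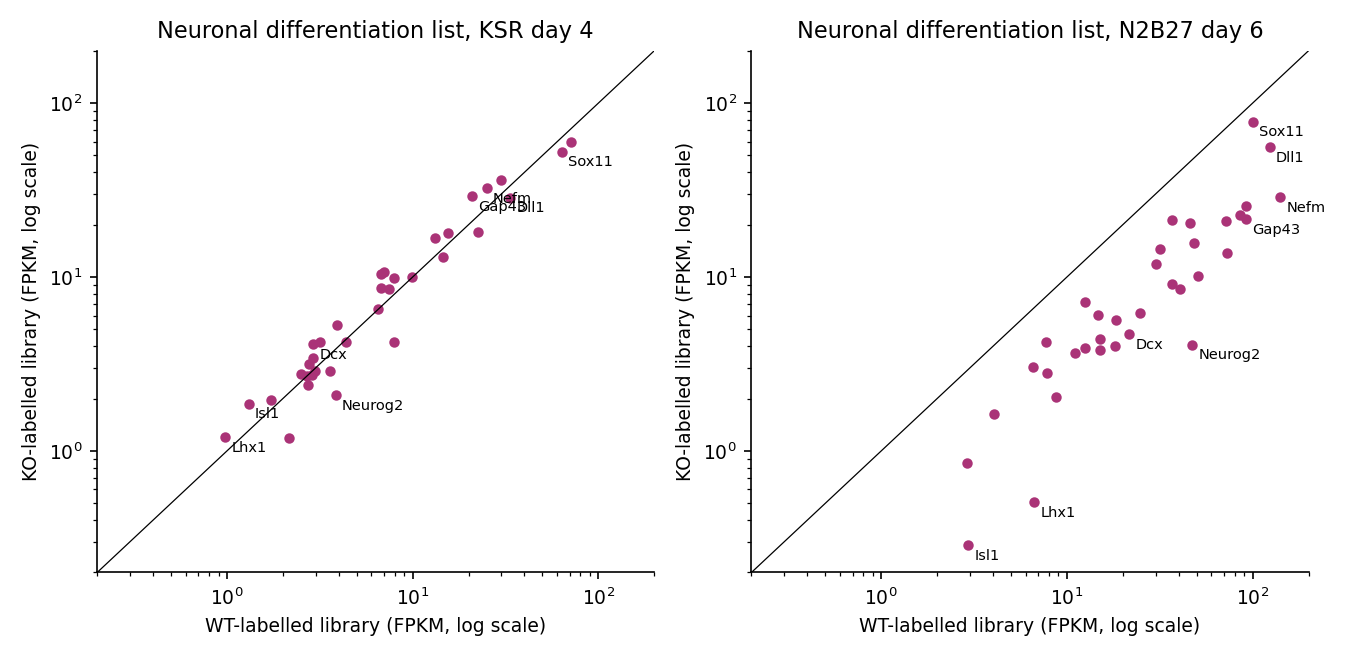
FPKM of the neuronal differentiation genes in the WT-labelled (x axis) and KO-labelled library (y axis) at KSR day 4 and N2B27 day 6, 1 point per gene on log axes, with a line of equal values. The list's median is 24.9 in the WT-labelled and 6.19 in the KO-labelled library of N2B27 day 6, and 6.48 and 5.29 at KSR day 4.

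At KSR day 4 the formative epiblast list had a median of 0.49 and glycolysis genes one of 0.44, both above all random lists, and trophoblast, endoderm, general pluripotency and naive pluripotency genes had 0.36, 0.21, 0.18 and 0.17. Pou5f1 had 47.8 FPKM under the WT and 90.4 under the KO label, the epithelial cadherin gene Cdh1 24.5 and 45.7, Cldn6 15.3 and 32.0 and Fgf8 8.94 and 15.1. Gmppb had 6.53 and 92.1, Mdga1 2.83 and 19.3, Hsd17b14 1.44 and 11.0 and Ndufa4l2 2.95 and 14.1. Cdkn1c had 23.6 and 3.06 and Kitl 5.08 and 0.788. Hox genes had −0.22, Notch targets −0.21 and progenitor genes −0.17.

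Within day 0, libraries of the same label differed more between the 2 series than libraries of both labels did within a series. The WT-labelled libraries of N2B27 and KSR day 0 differed by at least 2-fold in 1085 genes and the KO-labelled ones in 735, against 373 and 284 between labels. At N2B27 day 0 the stress response list had a median of −0.83 and Wnt targets 0.40, against −0.12 and 0.12 at KSR day 0. Foxn3 had 5.93 FPKM under the WT and 40.2 under the KO label, Mettl17 1.16 and 15.1, Ubap1l 28.0 and 3.50, Xlr5c 16.5 and 2.23 and Dcdc2a 5.07 and 0.162. At KSR day 0 germline genes had a median of 0.33, imprinted genes 0.23, p53 targets −0.28, 2-cell-like genes −0.26 and transition genes of epithelium and mesenchyme −0.23. At N2B27 day 0 these lists had −0.27, 0.05, −0.01, 0.05 and −0.13, so that germline genes went the opposite way. At KSR day 0 Zfp236 had 126 and 6.29 FPKM, Ece1 125 and 10.4, Plagl1, an imprinted zinc finger gene, 25.8 and 71.1, Cachd1 3.50 and 13.0, Xlr4c 2.14 and 11.1, and Pir 8.29 under the WT label and was listed at 0 under the KO label. The genes of chromosome 8 had a median of −0.35 at N2B27 day 0, against −0.01 at KSR day 0 and −0.00 at KSR day 4. At N2B27 day 6 it was −0.08. Both N2B27 medians lay below all of 1000 random sets matched for expression. Chromosome 5 at N2B27 day 6 (−0.008) and chromosome 6 at KSR day 0 (−0.06) and KSR day 4 (−0.03) were among others that did so. Members of lists given as examples were chosen after their values were seen. The p-values of limma measure the spread between these libraries and conditions alone, which may be technical. Those of camera set the genes of a list against the other genes, at a preset or estimated correlation. They are no measure of the spread between libraries alone.

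**Figure D4:**
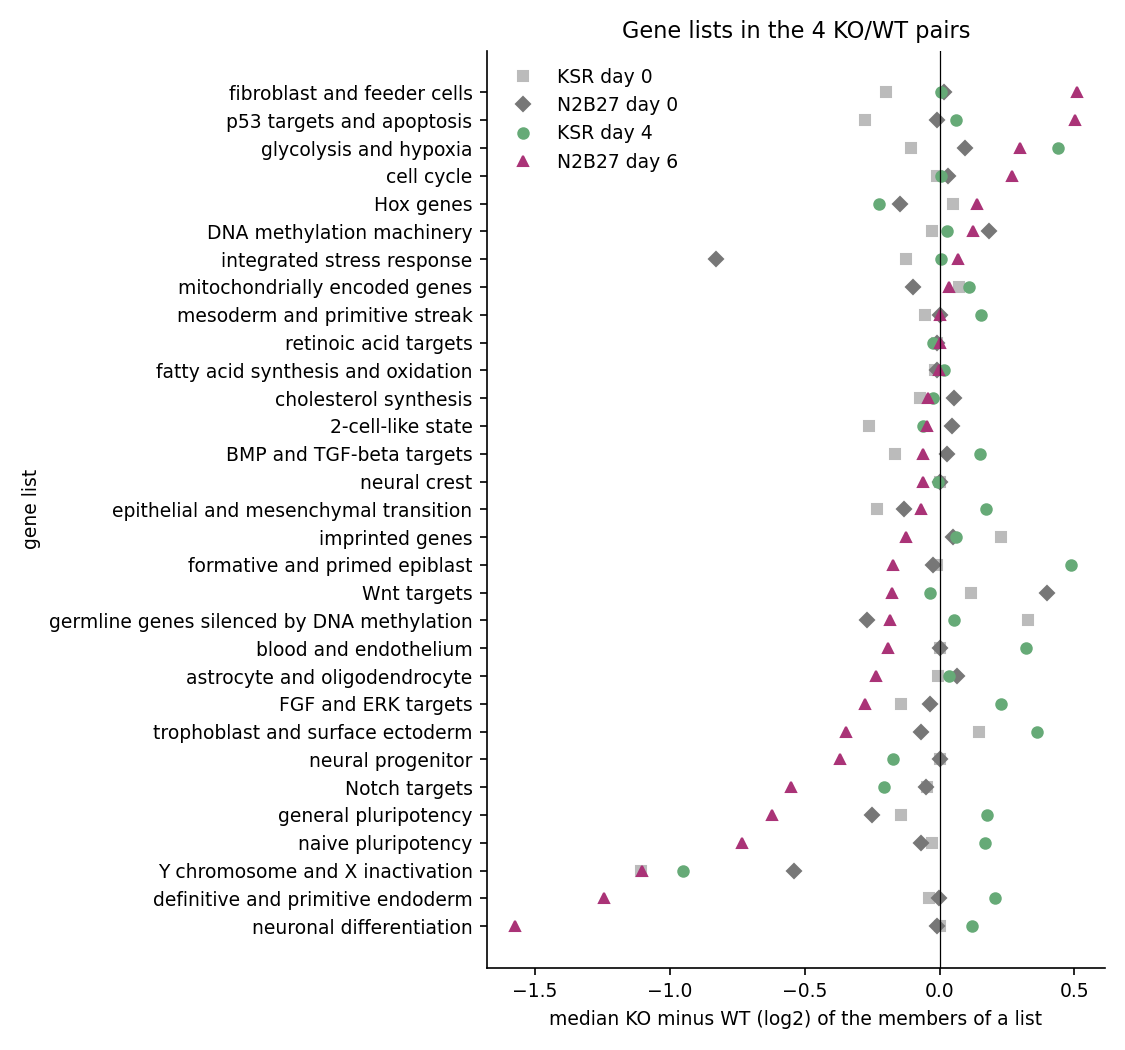
Median log2 difference, KO minus WT (x axis), of each gene list (y axis), with 1 symbol for each of the 4 single pairs. The neuronal list is at −1.57 in the N2B27 day 6 pair and 0.12 in the KSR day 4 pair.

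**Figure D5:**
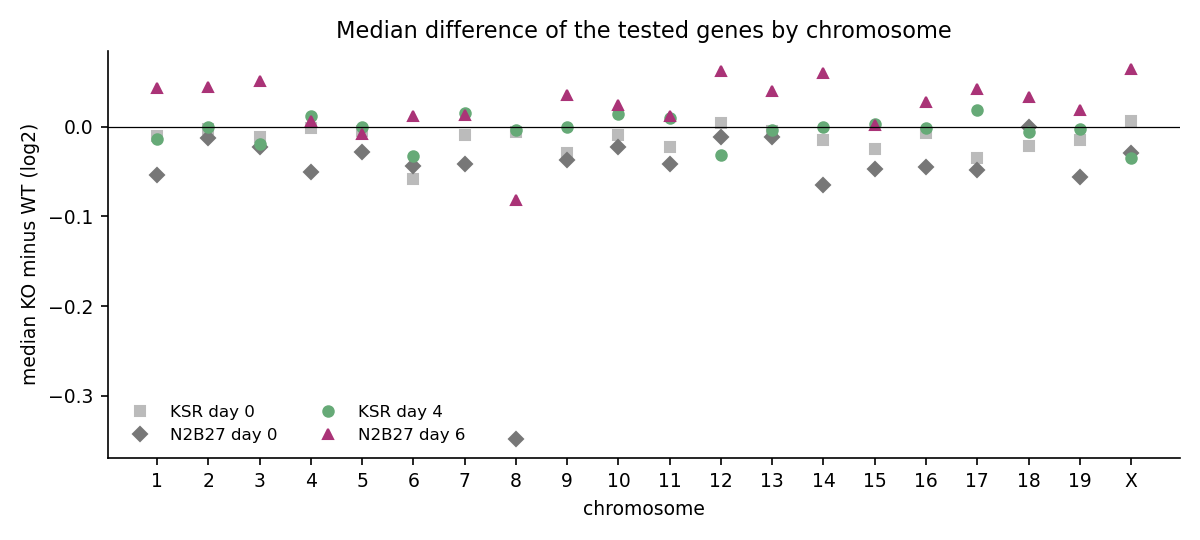
Median log2 difference, KO minus WT, (y axis) of the tested genes of each chromosome but Y (x axis), with 1 symbol for each of the 4 single pairs. Chromosome 8 lies at −0.35 in the N2B27 day 0 pair and at −0.01 in the KSR day 0 pair.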

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

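The tests of longer culture on the neuronal and on the rising genes and of an effect of the same size at KSR day 4 were chosen only after the result was seen.

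The KO minus WT difference after differentiation differed from that at day 0, by the test of the difference itself, for Gm7618 (5.75), a pseudogene with near-identical copies, and for 11 gene lists. The mean differences of the lists were −0.74 for neuronal, −0.48 for endoderm, −0.34 for Wnt, −0.31 for Notch, −0.25 for neural progenitor, −0.24 for naive pluripotency, −0.20 for imprinted and −0.17 for germline genes, and 0.33 for glycolysis, 0.44 for p53 and 0.52 for stress response genes. With an estimated correlation 0 of the 11 passed, and with fry 0 did. The negative means rested on the N2B27 day 6 pair. Without it those of neuronal, endoderm, naive pluripotency and germline genes were above 0. Those of Wnt, Notch, neural progenitor and imprinted genes were then smaller in size.

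In 14 lists the median over genes of the KO minus WT difference lay above 0 at KSR day 4 and below 0 at N2B27 day 6. There was 1 library per label, and the difference between the pairs was not tested. In 7 of them both medians lay outside the middle 95% of random lists matched for expression. The medians of these 7 were 0.17 and −0.73 for naive pluripotency, 0.18 and −0.62 for general pluripotency, 0.49 and −0.17 for formative epiblast, 0.12 and −1.57 for neuronal, 0.21 and −1.24 for endoderm, 0.36 and −0.35 for trophoblast genes and 0.23 and −0.28 for FGF and ERK targets.

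The low neuronal and pluripotency genes of the KO-labelled N2B27 day 6 library were weighed as 1 pattern. Scaling does not explain the neuronal part, since its median was −1.60 with median log2 ratio scaling and −1.57 without. A longer culture of the WT-labelled library, whose column name gives day 7, would leave the genes that fall on differentiation no lower in the KO-labelled library, and the 521 genes that fell at least 4-fold in both KSR pairs had a median of −0.11 (95% interval −0.16 to −0.08). That bound was set too close, since the intervals cover genes and not libraries, and with 1 library per label list medians other than that of the Y and X inactivation list reached 0.83 in size at day 0, a bound taken after the result was seen. A longer culture is therefore not settled for the pluripotency genes either way. For the neuronal genes, at −1.57 (−1.85 to −1.22), day and genotype cannot be told apart with 1 library per label, so a longer culture may still account for that part. The 753 genes that rose at least 4-fold in both KSR pairs had a median of −0.04 (−0.10 to 0.01), so rising genes at large were hardly lower, which does not decide it for the neuronal genes. The neuronal median at KSR day 4 was 0.12 (−0.04 to 0.20), so that pair showed no fall of the size seen at N2B27 day 6. It holds 1 library per label, so an effect of the deletion there stays open. So does an effect limited to N2B27 medium or to the later day, which was not tested.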

How the results depend on the processing

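The values without chromosomes 8 and Y were chosen only after the data were seen; all other alternatives were planned. Of the 41 named genes past the test, 561 of 570 values kept direction and call, 9 lost the call and 0 reversed, and all 1095 values of the 79 named genes not past it kept theirs. All of the 41 but Eif2s3y were picked as the largest changes on differentiation, and Gm14541 and Gm7618 are not among them. These values therefore do not show how well the calls of other genes held. Of the 57 list calls, 357 of 510 values kept direction and call, 142 lost the call, all 57 of them with an estimated correlation, and 11 reversed. Over 4 conditions, where 1 gene passed, 2 did with a pseudocount of 0.1 (Eif2s3y and Ddx3y), 0 with a pseudocount of 5, 0 with no filter, 0 without chromosomes 8 and Y, which removes Eif2s3y, and 0 to 1 in leave-one-out fits. At day 0 the 1 gene became 0 with a pseudocount of 5, with no filter, without the eBayes trend, with no block and in every leave-one-out fit. After differentiation and for the difference, 1 gene each became 0 with no filter and in every leave-one-out fit; for the difference an FPKM filter of 5 gave 2 (Gm7618 and Gm14541), and a pseudocount of 0.1 gave Gm14541 in place of Gm7618. Differentiation gave 1675 genes in WT-labelled and 1107 in KO-labelled cells with no filter, and 1409 to 4502 and 1744 to 3936 in leave-one-out fits. With pseudocounts of 0.1 and 5 the 2-fold counts by label were 1016 and 59 at KSR day 0, 835 and 51 at KSR day 4, 1111 and 67 at N2B27 day 0 and 1692 and 228 at N2B27 day 6. With a pseudocount of 5 those of differentiation were 2179 and 2829 in WT-labelled and 2080 and 2420 in KO-labelled cells (KSR and N2B27). With an estimated correlation 0 lists passed in any of the 6 comparisons, and with fry 1 over 4 conditions (Y and X inactivation) and 0 in the other 3 comparisons of labels. Leave-one-out fits called 6 to 10 lists over 4 conditions, 2 to 6 at day 0, 8 to 15 after differentiation and 5 to 16 for the difference. In leave-one-out fits the means over 4 conditions ranged from −0.532 to 0.0083 for neuronal, −0.429 to 0.0322 for endoderm, −0.319 to −0.0059 for naive pluripotency and −0.247 to 0.0367 for stress response genes. After differentiation those of neuronal, endoderm and naive pluripotency genes ranged from −1.56 to 0.0564, −1.21 to 0.171 and −0.790 to 0.149, and for the difference from −1.55 to 0.0721, −1.18 to 0.208 and −0.706 to 0.232, with germline genes from −0.450 to 0.104. The highest value of each, at which the direction turned (for naive pluripotency over 4 conditions that of the test alone), came without the N2B27 day 6 pair, except for stress response genes, where it came without the N2B27 day 0 pair, and germline genes, where it came without the KSR day 0 pair. With a pseudocount of 0.1 the means of the Y and X inactivation list were −2.92 over 4 conditions, −2.88 at day 0 and −2.96 after differentiation. Where a pair was left out, the lone remaining library was assumed to vary like the other groups. Fewer libraries leave fewer degrees of freedom in leave-one-out fits and testing with no filter adds genes near 0; for the other changes the cause was not tested. Pseudocounts act on genes of low FPKM, whose depth is unknown. A planned scaling and test of counts were not run, because the values are FPKM.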

Other observations

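The tests of the Y chromosome and of sequences it shares, of a second X chromosome, of the deletion as the reason for chromosome 8 or Y values, of the share of neurons and of other divisions of the libraries were chosen only after the result was seen.

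Metabolic and chromatin genes also changed on differentiation, in lists that did not pass as groups. Of 30 fatty acid genes 8 fell and 6 rose in WT-labelled cells and 10 fell and 6 rose in KO-labelled cells, or 9 and 6 and 11 and 7 adjusted over the list alone, and Cpt1a, which brings fatty acids into mitochondria for oxidation, fell by −4.56 and −4.86 log2. Of 27 glycolysis genes 7 fell and 0 rose in WT-labelled cells, the same numbers adjusted over the list alone, and in KO-labelled cells Hk1 (−2.29), Hk2 (−1.88) and Pfkp (−2.62) fell and Slc16a3 (0.99) rose, or 3 and 0 adjusted over the list alone. Among 18 genes of DNA methylation, the demethylase genes Tet1 (−2.50 in WT-labelled and −2.78 in KO-labelled cells) and Tet2 (−2.30 and −2.59) fell while Tet3 (2.81 and 2.49) and the methyltransferase gene Dnmt3a (2.21 and 2.63) rose. In WT-labelled cells 6 of these 18 rose and 5 fell, Tet1, Tet2, Zbtb38, Hells and Uhrf1, the same numbers adjusted over the list alone. In KO-labelled cells Dnmt3a, Tet3 and Uhrf2 rose and the same 5 fell, with Mbd3 rising as well adjusted over the list alone.

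A few loci and genes were looked at after their values were seen. Cdkn1c, Slc22a18 and Phlda2 are imprinted neighbours on chromosome 7. Phlda2 had 19.3, 8.62, 15.4 and 2.54 FPKM in the WT-labelled libraries of KSR day 0, KSR day 4, N2B27 day 0 and N2B27 day 6, and 2.999, 4.46, 5.55 and 0.517 in the KO-labelled ones. Cdkn1c had 2.32, 23.6, 0.813 and 104 and then 0.376, 3.06, 0.454 and 33.5, and Slc22a18 2.17 and 1.66 in the WT-labelled day 0 libraries and 0.286 and 0.749 in the KO-labelled ones. Other genes of the region changed less or the other way. Nap1l4 and Tssc4 were lower under the KO label in all 4 pairs, at N2B27 day 0 with 73.4 and 67.1 and with 27.6 and 23.3 FPKM, and Cd81 was lower in the day 0 pairs and higher in the others. Ascl2 and Kcnq1ot1, imprinted as well, were higher under the KO label in all 4 pairs, in part by little and at values near 0. Ascl2 had 2.05 and 4.08 FPKM at KSR day 0 and 0.822 and 1.20 at N2B27 day 0. It had 0.0486 and 0.311 at KSR day 4 and 0.1438 and 0.1445 at N2B27 day 6. Kcnq1ot1 had at most 0.332 FPKM. The mean over the 3 genes and 4 pairs was −1.13, and 12 of 15569 runs of 3 neighbouring tested genes were as low, 2 of them on the Y chromosome. Lss had 17.8 and 33.6 FPKM at KSR day 0, 24.1 and 58.1 at KSR day 4, 16.6 and 46.5 at N2B27 day 0 and 85.4 and 89.3 at N2B27 day 6, under the WT and the KO label.

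The Y-linked values were read as a hypothesis about the cells. The KO-labelled cells may lack a Y chromosome or its short arm: all 6 of the 6 short-arm protein-coding genes above 0 in every WT-labelled library (Eif2s3y, Ddx3y, Uty, Uba1y, Kdm5d and Zfy1) were at 0 in every KO-labelled one. Part of the signal assigned to Y remained, since 7 of the 11 tested genes were above 0 in all KO-labelled libraries. For 6 of the 7, at least 50% of their 50-base words also occur in transcripts of other chromosomes, so reads from there may be assigned to them. The exception, Gm47283, had 252 to 380 FPKM in the KO-labelled and 270 to 441 in the WT-labelled libraries. It lies at chromosome Y:90784738-90816464, far from the short-arm genes. Its words were sought in annotated transcripts alone, so its reads may still come from another chromosome. Its values therefore do not show that a part of the Y chromosome was kept, and whether the whole chromosome is absent was not settled. A second active X chromosome is argued against, since X-linked genes had medians of at most 0.0067 log2 at day 0 (95% interval of 0 to 0.0241, n = 628). Whether the deletion of Dip2c itself led to the loss cannot be told apart from the line, since 0 of the 4 KO-labelled libraries held such a gene above 0 and the deletion and the line share 1 label.

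Chromosome 8 gave another hypothesis. Some cells of the WT-labelled N2B27 day 0 library may have held an additional copy of chromosome 8, since 8 of its 8 stretches had medians of 0.24 to 0.56 log2 above the other day 0 libraries. The median by label at N2B27 day 6 was −0.08, and whether the WT-labelled library of that pair held such a copy was not tested. GC content and transcript length are argued against as the reason, since the median by label at N2B27 day 0 was −0.35 before and −0.35 after a fit on them (95% interval −0.39 to −0.32). Each day 0 library was set against the mean of the others. The chromosome 8 median was 0.37 in the WT-labelled N2B27 library and −0.11 in the WT-labelled KSR library. In the KO-labelled libraries it was −0.10 (N2B27) and −0.12 (KSR). So 1 WT-labelled library stood apart, and not the KO label. The median by label at KSR day 0 was −0.006 (95% interval −0.02 to 0.00, over genes and not libraries). Both KO-labelled libraries lay close to the WT-labelled KSR library. That argues against the deletion as the reason for the chromosome 8 difference at N2B27 day 0. With 1 library per label, other effects of the deletion on day 0 cells stay open.

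Another hypothesis was that the KO-labelled N2B27 day 6 library held a lower share of neurons, with every other cell type raised alike. The endoderm median of −1.24 (95% interval −1.40 to −1.02) argues against it for this pair alone. That median lies beyond the 0.83 that list medians, but for the Y and X inactivation list, reached in size at day 0. The bound was taken after the result was seen and came from the stress response list of the N2B27 pair of stem cells. It does not measure how far lists of cell types vary between differentiated libraries. The fibroblast median was 0.51, with an interval of −0.05 to 0.84 that includes 0. A change in which other cells were present may still play a part.

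Of the 35 divisions of the 8 libraries into 4 and 4, 8 part all 4 pairs. Among these the labels called 1 gene and the other 7 called 0 in limma, and 8 are too few for a share under 0.05. Another 24 part 2 pairs, leave the rest of the pairs whole and called 0 to 3 genes, so they are no measure of chance for the comparison of 4 pairs, and 3 could not be fitted with the condition as a block.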
